A study of Cyprinus carpio with 2 samples.

How the data were processed

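RNA was extracted from the immature testis and ovary of juvenile carp at 110 to 130 days post hatch and made into libraries with a kit for RNA sequencing, per the labels' protocols. There are 2 libraries, 1 per tissue, and the labels do not say how many fish each holds. The aligner, the assembler, the counting tool and the genome build are not given in the sources used here.

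The expression table and the lists for ovary and testis each hold a value per library for every unigene, per the file headers. In the deposited files these values are a signal, namely reads per unigene that the authors divided by 1 size factor per library. The values rose in steps of 2.31 units in ovary and 1.73 units in testis, computed from the low values. Each step was taken as 1 read, and whether it stands for 1 read or more was not tested. Dividing by these steps gave whole reads within 0.01 read for 22632 of the 22634 ovary values and 22633 of the testis values. The exceptions were foxk2 in both libraries and the ovary value of dmrta2 in the testis list. For these, rounded reads were used for read numbers and intervals, and the deposited values for scores and medians. The deposited log2 fold change is log2 of column B over column A, per the file headers and recomputed here for all 22487 unigenes of the table within 0.001. The deposited p-value is the authors' own, and no header says how it was computed or adjusted.

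The columns were assigned to tissues as follows. The headers call them A and B and do not name a tissue. All 127 unigenes of the authors' list titled for the ovary are higher in A, and all 171 of the list titled for the testis are higher in B, so A was taken as ovary and B as testis. This assignment uses list titles and the direction of values, not a column label, and an error in the titles would exchange every direction in the results. The oocyte list argues against such an error, since 57 of its 63 unigenes were at least 4-fold higher in A as deposited and 0 in B. Used in this way, the direction of the oocyte list is a check on the columns and not an independent result. No other column of values per sample was left unused.

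Of the 171 unigenes in the testis list, 147 have no row in the expression table used here. They were added to it, giving 22634 unigenes, and counts and medians for the table alone were computed as an alternative. Because those 147 were picked by the authors for being higher in testis, adding them moves lists that hold them. The table alone is not free of selection either. It holds all 127 unigenes of the ovary list but only 24 of the testis list, so its medians can lean toward ovary. Of the 9494 symbols, 4019 (42.3%) matched a symbol in the RefSeq annotation of assembly ASM1834038v1, which was used for names only. Several unigenes carried the same symbol for 6023 symbols. The carp genome is duplicated and a transcript set can hold several pieces of a gene, so reads can be divided among near-identical unigenes and the values of single unigenes are uncertain. Genes are called by the deposited symbol. For fshr, nanos3, fzd5 and foxo3b the deposited protein name is that of a related gene, and which name is right was not tested.

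The score of a unigene was log2 of (testis + 1) over (ovary + 1), in deposited units, a scale that understates differences of low unigenes. Unigenes at least 4-fold apart were counted where the higher library had at least 5 units. Ratios of reads carry exact Clopper-Pearson 95% intervals. Such an interval excluded the median ratio of all unigenes toward testis for 6235 unigenes and toward ovary for 6818, which compares these libraries and not the tissues. A count model was not fitted, since 1 library per tissue gives no spread between replicates. For each of 20 gene lists fixed before the data were examined, the median score over members with at least 1 unit in the higher library was set against the medians of 10000 random lists of the same size matched on deciles of expression. Members were matched on the first symbol of a row, allowing a paralogue suffix. Random lists drew each unigene independently, whereas a list can hold several unigenes of 1 gene, such as 31 for 10 symbols in extracellular matrix. The percentiles ignore this and can overstate how unusual a list is.

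Genes were named by a rule set before the data were examined: the 12 highest and 12 lowest scores among named unigenes with at least 10 units in the higher library, up to 4 members of each list with the largest absolute score, 16 gonad genes wherever a row names them, the 10 named unigenes with the largest deposited fold in each authors' list, and the 10 most abundant unigenes of each library. Folds are given relative to the median of all unigenes.

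Alternatives set before the data were examined were pseudocounts of 0.1 and 10, no filter on low values, floors of 5 and 20 units, rescaling to a median ratio of 1 or by a trimmed mean of log ratios, fold thresholds of 2 and 8, and summing the unigenes of one symbol. Chosen after seeing the data were the expression table alone, equal total reads, at least 100 reads per unigene, the number ranges, and random lists matched on number range as well. The counts were tested on simulated data, reads drawn for the 22634 unigenes with 200 changed. Of those, 45.5% were recovered at a true fold of 4 and 90.5% at 8. At a true fold of 4, 3.33% of unchanged unigenes were counted, against 0% of those with at least 100 reads. The simulation gave all unchanged unigenes 1 common ratio, rescaled to a median ratio of 1, and held counting error only. Partial recovery at a true fold equal to the threshold follows from this setting. These rates are therefore not error rates of the counts in the deposited values. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.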

Results

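RNA sequencing measured transcripts in immature gonads of juvenile common carp (Cyprinus carpio) at 110 to 130 days post hatch, with 1 testis library and 1 ovary library. Values were given for unigenes, numbered transcript units, each carrying a protein and gene name. The 22634 unigenes analysed held 4311799 ovary reads and 1926860 testis reads, with a median of 35 ovary and 29 testis reads per unigene. These sums cover the annotated unigenes in the tables and are not the depth of the libraries. All read numbers here take 1 step of the deposited values as 1 read. With 1 library per tissue, no difference below has a replicate check, and no p-value was computed. The 95% intervals are exact intervals for the ratio of the reads and cover counting error only. The value columns of the tables do not name the tissues. Column A was taken as ovary and column B as testis because the authors' list titled for the ovary is higher in A throughout and the one titled for the testis is higher in B throughout. Every direction below was assigned from those titles. The oocyte list argues against an exchange of the columns, since 57 of its 63 unigenes were at least 4-fold higher in A as deposited and 0 in B.

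The first comparison asked which transcripts differed between the juvenile testis and ovary. The ovary library was richer in transcripts of the egg envelope and the growing oocyte, such as zp2.2, zp3a.2, btg4 and gdf3. The testis library was richer in transcripts of the male somatic pathway, such as amh, Dmrt1-1, wt1a and cldn11a, and in collagens, although all 4 of these genes and every collagen named below are in the authors' list for testis. Germ cell transcripts, and ribosomal and reference transcripts, went both ways.

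In the deposited values, 1329 unigenes were at least 4-fold higher in testis and 5022 at least 4-fold higher in ovary, among 21649 with at least 5 units in the higher library. The median unigene was 1.78-fold higher in ovary, a log2 ratio of -0.83, so this split follows the scaling. Rescaled to a median ratio of 1, the counts were 2986 in testis and 2564 in ovary, and the trimmed mean of log ratios gave 3000 and 2491. With equal total reads they were 4930 and 1283. Folds and list medians below are therefore relative to the median of all unigenes. No unigene was listed at 0 in either library, and both lowest values were 1 read. This held even for the 3669 unigenes with under 10 reads in all, so unigenes read in one library alone appear to be left out. The count of unigenes listed in one library alone, 0, therefore says nothing about transcripts present in only one tissue. Counts and medians here cover unigenes read in both libraries. The ratio also moved with the unigene number. The 11904 unigenes numbered below 23700 had a median log2 ratio of -1.79, and the 10730 from there on had 0.32. Each list median is therefore given with its percentile among 10000 random lists matched on expression, and again with lists matched on expression and on these number ranges. The brackets also give the list median within each range that holds at least 3 of its unigenes, relative to the median of that range. Random lists are not centred on 0. Matched on expression and number range, their median relative to all unigenes was -0.89 for the oocyte list and -0.74 for the ribosomal list. It was 0.55 for the testis somatic, hormone receptor and extracellular matrix lists. The data include 147 unigenes that come from the authors' testis list alone. They were picked by the authors for being higher in testis, so that choice fixed their direction. Medians without them can lean toward ovary, since all 127 unigenes of the authors' ovary list remain. Among the genes named below they are wt1a, cldn11a, sycp1, meiob, fshr, esr2b, rxrba, mcm6, foxo3b, bmpr2a, col5a1, col1a2, col6a1, col12a1b, lyz, b2m, eef1a1b, ccdc79, 1 unigene of dmrta2 and the 12 unigenes with the highest scores.

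**Figure D1:**
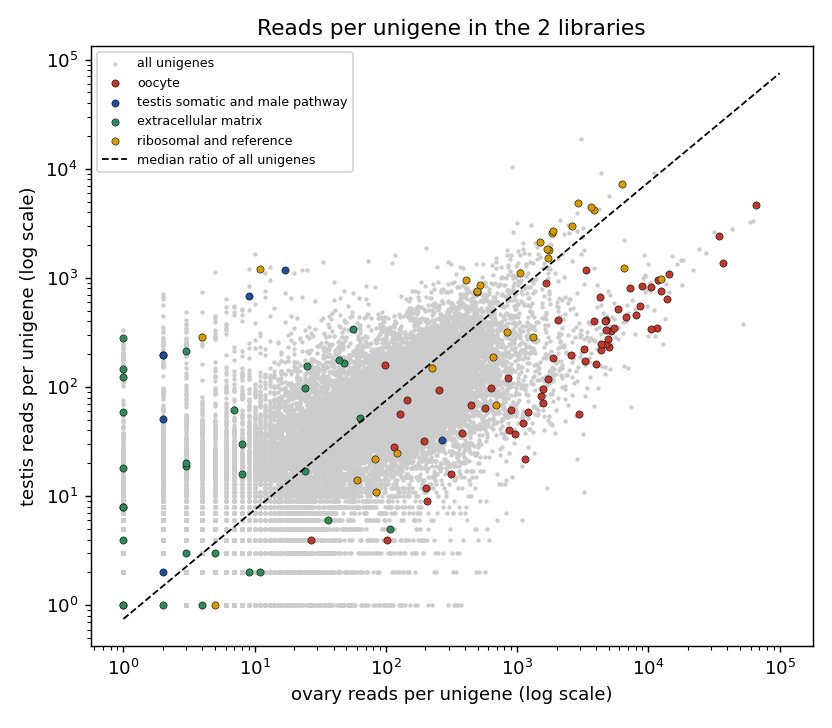
Testis reads against ovary reads for each of 22634 unigenes, both on log axes, with 4 gene lists in colour and a dashed line at the median ratio of all unigenes. The 63 oocyte unigenes lie mostly below the line, with a median of -3.45 on the log2 scale relative to it, and 6 of the 7 unigenes of the testis somatic list lie above it.

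The testis somatic and male pathway list had 7 measured unigenes, of which 6 lay above the median of all unigenes and 1, dmrt2a, below it. Their median was 6.49 (percentile 100, or 100 with number range; 5.40 from 23700 on). Transcripts of amh (Unigene_64952), the anti-Müllerian hormone made by Sertoli cells, were 92.2-fold (95% interval 57.3 to 159) higher in testis, from 17 ovary and 1175 testis reads. Dmrt1-1 (Unigene_60277), a transcription factor of testis development, was 131-fold (95% interval 35.9 to 1092) higher, from 2 ovary and 197 testis reads. The kidney and gonad factor wt1a was 130-fold (95% interval 35.5 to 1081) higher and the tight junction gene cldn11a 101-fold (95% interval 53.1 to 223) higher. For sox9a, a factor of Sertoli cells, 2 ovary and 51 testis reads gave 34-fold (95% interval 8.94 to 288). The wt1a and cldn11a unigenes come from the authors' testis list and have no row in the expression table used here. Without such unigenes the list median was 4.82 over 5 unigenes, but amh, Dmrt1-1 and sox9a are in the authors' testis list too. Only dmrt2a and tbx1, the latter with 2 ovary and 2 testis reads, are free of that selection. Unigenes that the authors listed for being higher in testis are not independent evidence of the direction of this list.

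The oocyte list had 63 measured unigenes, 62 of them below the median of all unigenes, with a median of -3.45 (percentile 0, or 0 with number range; -2.73 below 23700 and -4.33 from 23700 on). After rescaling to a median ratio of 1, 55 were at least 4-fold higher in ovary and 0 in testis. The egg envelope gene zp2.2 had the highest ovary value (Unigene_19459, 66230 ovary and 4665 testis reads) and was 10.6-fold (95% interval 10.3 to 11) higher in ovary. For zp3a.2 (Unigene_20698), another envelope gene, the difference was 20.3-fold (95% interval 19.2 to 21.5). The growth factor gdf3 was 39-fold (95% interval 30 to 51.6) higher, the carbonic anhydrase ca15b 38.9-fold (95% interval 25.6 to 62.4) higher in its most uneven unigene, or 16.5-fold with both unigenes summed, and btg4, which acts in the clearance of maternal transcripts, 24.9-fold (95% interval 22.4 to 27.8) higher. Both unigenes of gdf9, an oocyte growth factor, were higher in ovary, by 17.2-fold and 14.6-fold. The unigenes of bmp15 differed less, by 4.59-fold and 3.11-fold. Transcripts of zar1, needed at the start of embryonic development, were 11.8-fold (95% interval 10.6 to 13.2) higher in ovary, and zar1l 6.75-fold higher. None of these directions changed under the other scalings.

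Germ cell and meiosis transcripts went both ways. The germ cell and piRNA list, 37 unigenes, had a median of 0.55 (percentile 99.7, or 99.9 with number range; 0.60 below 23700 and 0.18 from 23700 on). Its nanos3, an RNA-binding protein of germ cells, was 35.6-fold (95% interval 26.8 to 48.2) higher in ovary, and pou5f3 15.6-fold higher. The 2 dazl unigenes, which encode another RNA-binding protein of germ cells, were 1.43-fold and 1.46-fold higher in testis relative to the median, from 931 ovary and 1001 testis reads and 484 ovary and 531 testis reads, but 1.24-fold and 1.22-fold higher in ovary as deposited. Values for lin28a were low, with 28 ovary and 1 testis reads in its most uneven unigene and 30 ovary and 2 testis reads in both together. The meiosis list, 29 unigenes, had a median of -0.28 (percentile 33.8, or 14.7 with number range; 0.16 below 23700 and 0.59 from 23700 on). Its sign was not stable, since the median was above 0 within both ranges and 0.65 with the unigenes of one symbol summed. The synaptonemal complex gene sycp1 was 244-fold (95% interval 43.2 to 9689) higher in testis, from 1 ovary and 183 testis reads. The recombination gene meiob was 215-fold (95% interval 58.9 to 1780.2) higher. Cyclin A1, ccna1, was 10.1-fold (95% interval 9.6 to 10.6) higher in ovary, and sycp2l 7.15-fold higher. The spermatid and sperm axoneme list, 68 unigenes, had a median of 0.48 (percentile 56.4, or 76.7 with number range; 0.49 below 23700 and 0.47 from 23700 on), and its largest difference was in spaca4l, 85.6-fold (95% interval 67.1 to 111) higher in ovary in its most uneven unigene and 32.1-fold with its 3 unigenes summed. The spaca4l unigenes entered by the suffix rule, as a form of spaca4, and held 20875 of the list's 22812 ovary reads. Whether spaca4l encodes a sperm protein in carp was not tested, so it is not evidence of sperm transcripts in ovary. In the same list cfap100 was 17.1-fold and dnai1.2 9.25-fold higher in ovary. These named members, picked for the largest absolute scores, do not stand for the list. After rescaling to a median ratio of 1, 12 of its unigenes were at least 4-fold higher in testis and 6 in ovary. Of all 68, 36 lay above the median of all unigenes and 29 below.

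The ovary somatic and female pathway list, 21 unigenes, had a median of 0.29 (percentile 74.4, or 73.8 with number range; -0.24 below 23700 and -0.40 from 23700 on). Its sign also changed within both ranges. The list covers 9 of its 22 symbols, without cyp19a1 and foxl2, and 13 of its 21 unigenes are also in other lists. It is thus only a partial view of the female pathway. Its largest differences were toward testis, in 3 unigenes of the authors' testis list. A unigene with the symbol fshr, whose deposited protein name is thyrotropin receptor, had 1 ovary and 191 testis reads. The estrogen receptor esr2b was 184-fold (95% interval 62.4 to 894) higher in testis, and gata6 64-fold (95% interval 17.2 to 536) higher. The lhx9 unigene farthest from the median was 6-fold (95% interval 1.41 to 53.8) higher in ovary, from 16 ovary and 2 testis reads, and all 3 lhx9 unigenes together 2.3-fold higher. Hormone and nuclear receptors, 25 unigenes, had a median of 1.26 (percentile 99.4, or 98.5 with number range; 0.26 below 23700 and 1.32 from 23700 on), with rxrba 158-fold (95% interval 43.3 to 1312) higher in testis. The most uneven nr3c1 unigene had 1 ovary and 21 testis reads, and all 3 nr3c1 unigenes together 48 ovary and 276 testis reads. Without the unigenes found in the authors' testis list alone, this median was 0.59 over 22 unigenes, a value that can lean toward ovary. Steroidogenesis, 32 unigenes, had a median of -1.06 (percentile 0.14, or 1.56 with number range; -0.61 below 23700 and -0.52 from 23700 on). The lipoprotein receptor scarb1 was 10.6-fold (95% interval 7.84 to 14.6) higher in ovary, hsd17b12a 8.18-fold and srd5a1 5.25-fold higher, and the most uneven hsd11b1l unigene held 2 ovary and 35 testis reads. Both hsd11b1l unigenes together held 191 ovary and 68 testis reads. No row matched the symbols gsdf, cyp19a1, foxl2, ddx4, sycp3, star and cyp17a1, so these were not analysed here.

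Cell cycle and cyclin transcripts, 94 unigenes, had a median of -1.05 (percentile 0.05, or 0.01 with number range; -1.15 below 23700 and -1.15 from 23700 on), with 36 at least 4-fold higher in ovary and 5 in testis after rescaling to a median ratio of 1. The mitotic inhibitor fbxo5 was 24.3-fold (95% interval 18.5 to 32.5) higher in ovary. The replication helicase subunit mcm6 was 163-fold (95% interval 63.4 to 602) higher in testis, whereas the related mcm6l had 375 ovary and 1 testis reads in its most uneven unigene. The Sox, Fox and Dmrt list, 19 unigenes, had a median of -1.09 (percentile 0.13, or 0.07 with number range; -1.48 below 23700 and 3.68 from 23700 on) and members at both ends, with foxh1 20.6-fold higher in ovary and foxo3b 66.5-fold higher in testis. The 3.68 from 23700 on rests on 7 unigenes. Among them are Dmrt1-1, sox9a, foxo3b and 1 unigene of dmrta2, all in the authors' testis list. Without the unigenes that come from that list alone, the median of all members was -1.46 over 17 unigenes. The dmrta2 unigene in the authors' testis list held 2 ovary and 247 testis reads, rounded from a value that is not whole reads. Yet all 3 dmrta2 unigenes together held 261 ovary and 277 testis reads. The TGF-beta list, 36 unigenes, had a median of -0.05 (percentile 37.2, or 70.1 with number range; -0.46 below 23700 and 1.02 from 23700 on), with amh and the receptor bmpr2a higher in testis, the latter 120-fold (95% interval 51 to 371), and gdf9 higher in ovary. The Wnt list, 63 unigenes, had a median of -0.19 (percentile 7.2, or 22.9 with number range; -0.11 below 23700 and 0.47 from 23700 on), with lef1 7.18-fold higher in ovary. The 3 unigenes of fzd5 together were 15.1-fold higher in ovary, and the 4 of lrp5 together held 22 ovary and 78 testis reads.

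Extracellular matrix transcripts, 31 unigenes, had a median of 2.27 (percentile 100, or 100 with number range; 0.65 below 23700 and 1.85 from 23700 on). Of these, 18 were at least 4-fold higher in testis and 2 in ovary after rescaling to a median ratio of 1. Collagens led the list, with col5a1, col1a2 and col6a1 at 1 ovary read each against 281, 147 and 123 testis reads, and col12a1b 95.1-fold (95% interval 32.1 to 465) higher in testis. These 4 collagens come from the authors' testis list alone, and without such unigenes the list median was 2.09 over 27 unigenes. Of the 5 lists for other tissues, only skeletal muscle had a median outside the central 95% of random lists. The erythrocyte list, 9 unigenes of tfr1a, tfr1b and epb41b, had a median of 1.26 (percentile 96.9, or 88.1 with number range; 1.30 below 23700 and 0.40 from 23700 on), with the tfr1a unigene 3.43-fold higher in ovary and the tfr1b and epb41b unigenes that lay farthest from the median at 20 testis reads or fewer. The immune list, 12 unigenes, had a median of 0.69 (percentile 90.7, or 89.4 with number range; -1.99 below 23700 and 1.78 from 23700 on), but -1.28 over 7 symbols with the unigenes of one symbol summed, so it has no stable direction. It held mpx, a myeloid peroxidase, 114-fold (95% interval 44.4 to 421) higher in ovary in its most uneven unigene and 41.7-fold with both summed, ccl19a.2 29.8-fold and il1b 18.2-fold higher in ovary, and the lysozyme lyz at 1 ovary and 222 testis reads. Skeletal muscle transcripts, 23 unigenes, had a median of -1.14 (percentile 0, or 0.01 with number range; -0.60 below 23700 and -0.59 from 23700 on), with tnni2b.1 43.7-fold (95% interval 25.4 to 82.5) higher in ovary, myhz1.1 5.62-fold higher and TNNT3 at 18 ovary and 2 testis reads. The liver, pancreas and gut list, 20 unigenes, had a median of -0.53 (percentile 2.63, or 7.89 with number range; 0.04 below 23700 and 0.03 from 23700 on), with the insulin gene ins 34.5-fold (95% interval 16.6 to 86.5) and c3a.6 32.8-fold higher in ovary and apoa2 at 37 ovary and 1 testis reads. The adipose, kidney and pigment list had 5 unigenes and a median of 0.55 (percentile 54.9, or 36.2 with number range; 1.39 from 23700 on), with oca2 9.48-fold higher in ovary and slc12a3 8.15-fold higher in testis.

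Ribosomal and reference transcripts, 30 unigenes, had a median of 0.51 (percentile 99.98, or 100 with number range; -0.31 below 23700 and -0.52 from 23700 on). Its sign changed within both ranges, which held 18 and 12 of its unigenes. The random lists matched on expression and number range had a median of -0.74, so the percentile compares with unigenes of like expression and not with 0. In ovary, gapdh was 9.57-fold (95% interval 8.97 to 10.2) higher, and hprt1 7.68-fold in its most uneven unigene but 2.97-fold with both summed. In testis, b2m was 147-fold and eef1a1b 95.3-fold higher. The 4 mitochondrially encoded unigenes had a median of 2.0 (percentile 99, or 93.9 with number range; 0.86 from 23700 on), and all 4 lie from 23700 on. COX1 was 8.14-fold (95% interval 7.84 to 8.46) and COX3 15.2-fold (95% interval 14.2 to 16.3) higher in testis in their most abundant unigenes. The list rests on these 2 symbols, with 2 unigenes each. The most abundant COX1 unigene held 3055 of 3071 ovary and 18655 of 18667 testis reads. For COX3 it held 915 of 919 and 10414 of 10420, so the other 2 unigenes had few reads. In all, 11 of the 20 lists had a median outside the central 95% of random lists, 6 above and 5 below, and 5 and 5 with lists also matched on number range. Among those above, the testis somatic, hormone receptor, extracellular matrix and ribosomal lists hold 2, 3, 4 and 2 unigenes from the authors' testis list alone. Their percentiles partly reflect that selection, and no percentile without these unigenes is given here. Against 0 and not against the median of all unigenes, 10 lists had a median below 0 as deposited and above 0 with equal total reads. These were the ovary somatic, germ cell, meiosis, spermatid, TGF-beta, Wnt, immune, liver, adipose and ribosomal lists.

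**Figure D2:**
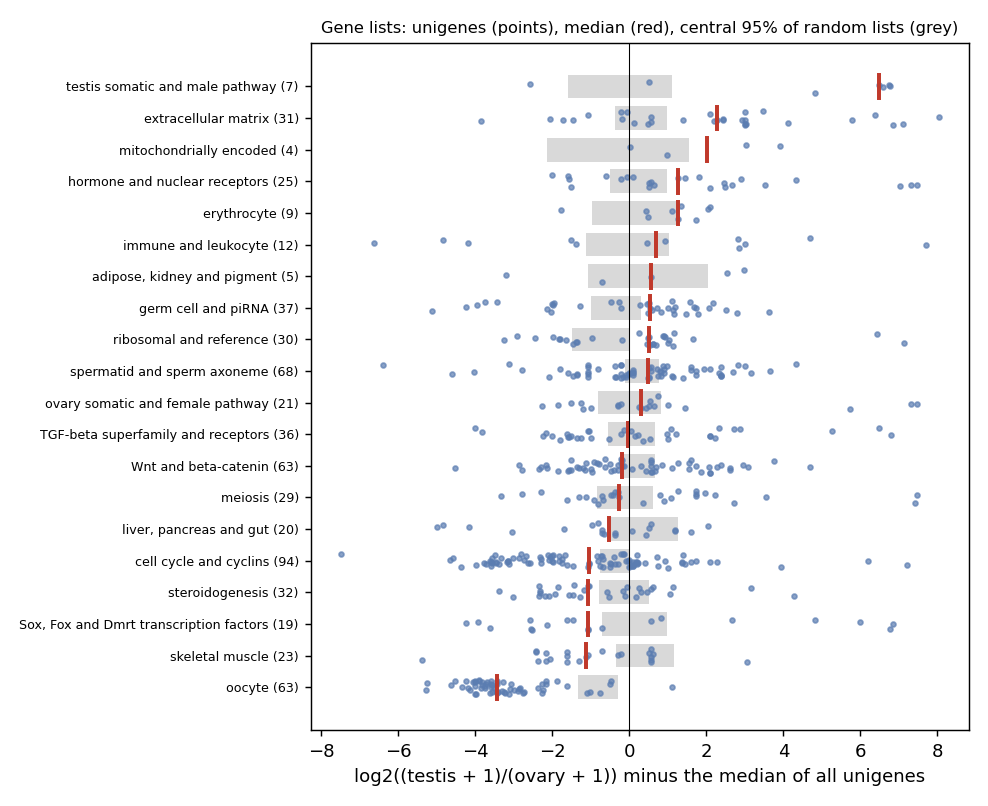
Log2 of testis over ovary minus the median of all unigenes, with 1 unit added to each value, for the unigenes of 20 gene lists (number of unigenes in brackets). Points are unigenes, red lines are list medians, and grey bars are the central 95% of the medians of 10000 random lists matched on expression; the oocyte median is -3.45 and the extracellular matrix median 2.27.

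Among unigenes with a usable name and at least 10 units in the higher library, the 12 highest testis to ovary scores rested on 1 to 5 ovary reads each. The intelectin itln3 had 2 ovary and 718 testis reads, 479-fold (95% interval 132 to 3960.1) higher in testis, and stmn1b, a stathmin, was 450-fold (95% interval 124 to 3723) higher. The tyrosine kinase csk was 302-fold (95% interval 129 to 931) higher and the lipid transporter abca1a 246-fold (95% interval 95.5 to 904) higher. The others were slc16a9b, npsn, col5a1, tpm4a, tcf23, phyhipl, bhlhe40 and col7a1. All 12 come from the authors' testis list and have no row in the expression table used here. The 12 lowest scores rested on 1 to 22 testis reads. In ovary, ponzr2 was 96.6-fold (95% interval 63.7 to 154) higher, cyp2k21 136-fold (95% interval 62.1 to 370.4) higher, foxp3a 213-fold (95% interval 58.6 to 1760) higher and il21 182-fold (95% interval 50 to 1503) higher. The others were mcm6l, klhl43, ube2e2, npffl, wfdc2, tmem26b, mpx and noxo1a. Summing the unigenes of one symbol changed some of these. The most uneven ube2e2 unigene had 341 ovary and 1 testis reads, but its 3 unigenes together held 921 ovary and 982 testis reads, and the 3 of mcm6l held 2020 ovary and 163 testis reads. The 24 unigenes named wfdc2 together held 24233 ovary and 1934 testis reads.

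**Figure D3:**
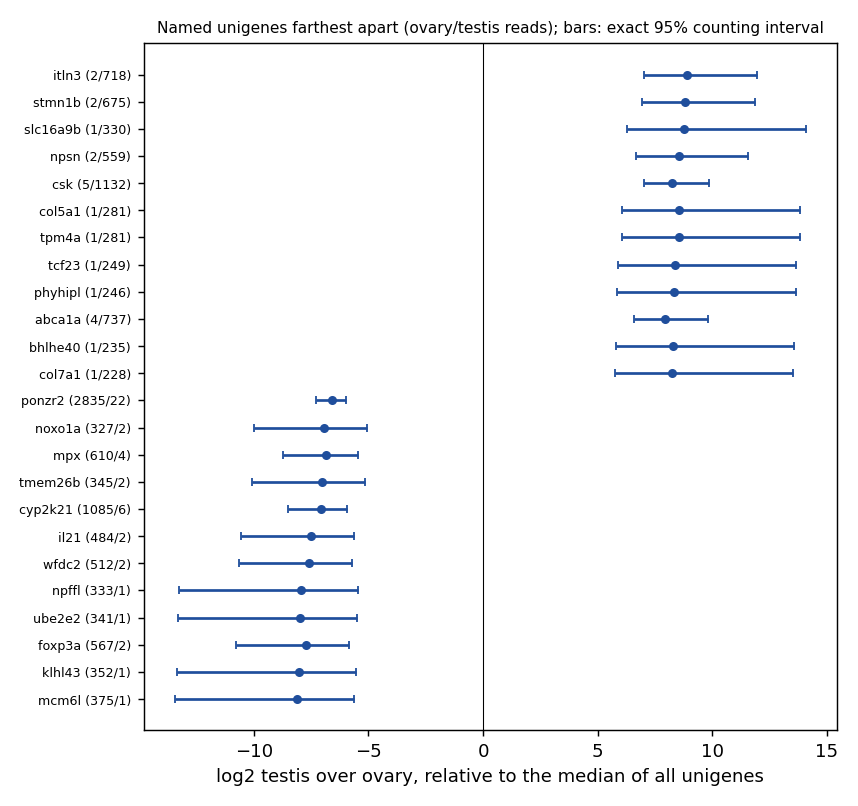
Log2 testis over ovary relative to the median of all unigenes for the 12 highest and 12 lowest named unigenes, with exact 95% counting intervals as bars and the ovary and testis reads after each name. The 12 toward testis have 1 to 5 ovary reads, and the 12 toward ovary have 1 to 22 testis reads.

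The 10 most abundant ovary unigenes carried 10.2% of the ovary reads and the 10 most abundant testis unigenes 4.07% of the testis reads. In ovary these were 2 unigenes of zp2.2, 3 of LOC100148225, 2 of the cystatin cst3, and 1 each of zp3a.2, ccna1 and an uncharacterized protein. The cst3 unigene with most reads was 13.9-fold (95% interval 13.4 to 14.4) higher in ovary and the uncharacterized Unigene_17941 104-fold (95% interval 93.9 to 115) higher. In testis the list was COX1, COX3, the translation factors eef2b, eef1a and etf1b, the ribosomal proteins rpl3 and rplp0, the actin actba, cecr2 and zp2.2. Relative to the median, eef2b was 2.81-fold higher in testis, rpl3 1.54-fold, rplp0 1.63-fold and eef1a 1.09-fold. As deposited, eef2b was still higher in testis, whereas rpl3, rplp0 and eef1a were higher in ovary, by 1.16-fold, 1.09-fold and 1.63-fold. The actba unigene in this group was 2.22-fold higher in testis, its other unigene 3.96-fold higher in ovary, and both together 1.16-fold higher in ovary.

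The authors' lists of unigenes higher in one tissue held 127 unigenes for ovary, 87 of them with a usable gene name, and 171 for testis, 140 of them named, and shared 0. Their directions served to assign the columns and are not an independent result. All 127 of the ovary list have a row in the expression table used here, against 24 of the testis list. Every unigene of both lists was at least 4-fold apart in the deposited values, by a median of 84-fold in the ovary list and 78.8-fold in the testis list. In 65 of the 127 and 116 of the 171, the lower library held 1 to 3 reads. By number, 126 of the 127 lay below 23700 and all 171 lay from it on. Among named unigenes in the authors' deposited ovary list, the largest log2 fold change was -8.97 for mcm6l, with a p-value of 0.00498. Among those in the authors' deposited testis list it was 8.13 for itln3, with a p-value of 0.00895. The itln3 values in the same row give 8.07, a mismatch that many unigenes of the testis list share. For amh the authors' deposited table gave 5.70 and a p-value of 0.0471, and for Dmrt1-1 it gave 6.21 and 0.0338. Unigenes without a usable name were not ranked. The other unigenes among the 10 largest named ones were klhl43, ube2e2, npffl, foxp3a, wfdc2, il21, cyp2k21, tmem26b and noxo1a for ovary. For testis they were stmn1b, slc16a9b, tpm4a, npsn, col5a1, tcf23, phyhipl, bhlhe40 and col7a1.

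**Figure D4:**
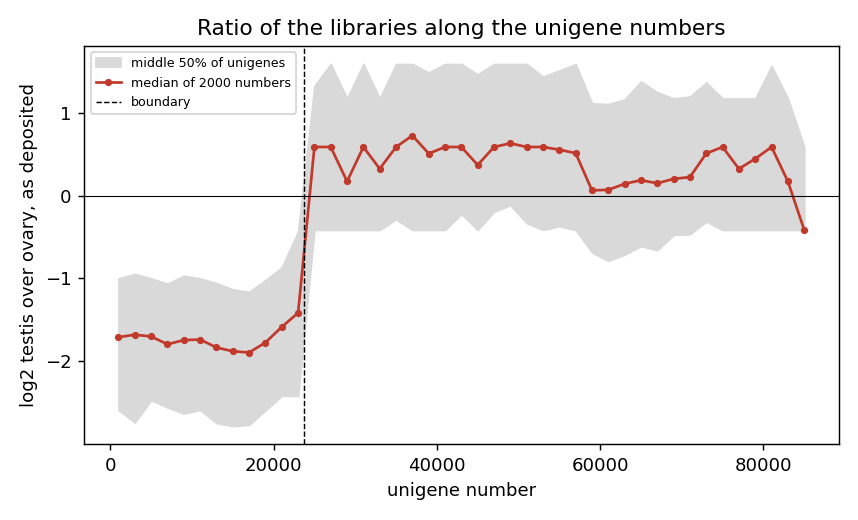
Median log2 testis over ovary as deposited (red points) and the middle 50% of unigenes (grey) in steps of 2000 unigene numbers, with a dashed line at 23700. Medians over all unigenes are -1.79 below that number and 0.32 from it on.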

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

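The expression table alone, equal total reads, the minimum of 100 reads and the number ranges were chosen after seeing the data. The counts of unigenes at least 4-fold higher in testis and in ovary, 1329 and 5022, were 2986 and 2564 when rescaled to a median ratio of 1, 3000 and 2491 by the trimmed mean of log ratios, and 4930 and 1283 with equal total reads. They were 3364 and 10152 at a fold threshold of 2, 544 and 1990 at 8, and 483 and 3090 with at least 100 reads in both libraries together. A pseudocount of 10 gave 683 in testis. For the ovary count under that pseudocount, and for both counts under the other alternatives, the value was within 1.5 times. Relative to all unigenes, the oocyte median of -3.45 was -3.68 with a pseudocount of 10, -3.16 with the unigenes of one symbol summed, -2.73 among numbers below 23700 and -4.33 from there on. The extracellular matrix median was 3.17 with symbols summed. Among numbers from 23700 on, the median was -0.40 for the ovary somatic list, 1.02 for the TGF-beta list, 3.68 for the Sox, Fox and Dmrt list and 0.40 for the erythrocyte list. The sign of the median changed under at least 1 alternative in 9 of 20 lists: ovary somatic, meiosis, TGF-beta, Wnt, Sox, Fox and Dmrt, immune, liver, adipose and ribosomal. For all of these the 95% interval from resampling includes 0, so they are not counted as reversed. Beyond the different unigenes or threshold that an alternative uses, the cause was not tested. Of 202 values under alternatives, 180 stayed within 1.5 times for counts or within the 95% interval from resampling a list's members for medians, and 22 moved further. Of the 202, 46 were fixed or nearly fixed in advance: no filter on low values, rescaling to a median ratio of 1 for medians already relative to all unigenes, the floors for unigenes listed in one library alone, and a 4-fold limit on the authors' lists. Of the other 156, 134 stayed within those bounds. The interval is wide for short lists, such as -2.85 to 2.92 for the immune list, so staying within it is a weak check for them. Lists with fewer than 3 unigenes in a setting have no value there. No paired analysis was possible because each tissue has 1 library, and for the same reason no replicate could be left out. With 1 to 3 reads in the lower library, intervals of single unigenes span over 10 times.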

Other observations

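The tests and gene groups in this part were all chosen after the values had been seen. Among 194 families of unigenes that share the letters before the first digit of their symbol, each with at least 15 unigenes, 48 had a median outside the central 95% of random lists matched on expression, and 31 of these also with lists matched on number range. Unigenes of one symbol were separate members here too, so both counts can be too high. The 24 unigenes under the single symbol wfdc2 had a median of -2.96 relative to all unigenes. The rpl and rps families of ribosomal proteins had 0.91 over 35 unigenes and 0.53 over 54, and as deposited, without the shift of 0.83, the rps median lay below 0. The abca lipid transporters had 1.89 over 21 unigenes and the col family 2.53 over 17. Both include unigenes that the authors picked for being higher in testis, and no median without these is given here. The tdrd family of piRNA proteins had 0.98 over 18 unigenes. The mcm family of minichromosome maintenance genes had 0.03 over 32 unigenes, with 16 above the median of all unigenes. Also, rnf17, a tudor domain gene of the piRNA pathway, was 12.3-fold (95% interval 10.6 to 14.3) higher in testis in its most abundant unigene, and ccdc79, a synonym of the meiosis gene terb1 and known from the authors' testis list alone, 137-fold (95% interval 37.4 to 1136) higher.

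The ratio of the libraries changed abruptly at unigene number 23700, from a median log2 ratio of -1.79 below it to 0.32 from it on. Few reads per unigene do not account for this, since the gap was still 1.78 among unigenes with at least 100 reads. Different genes in the ranges do not account for the whole of it either: for 1419 symbols with such unigenes in both ranges, the range from 23700 on was higher by a median of 1.12 within a symbol, and in 92.7% of symbols. A candidate explanation is that contigs assembled from one library take up more reads of that library, which predicts such a difference within symbols. Since 126 of 127 unigenes of the authors' ovary list and 0 of 171 of the testis list lie below 23700, single extreme unigenes may partly reflect the assembly, as in ube2e2 and dmrta2, whose unigenes disagree; how the unigenes were numbered is not given in the sources used here.

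Oocyte transcripts were also found in the testis library. Among 27 oocyte unigenes below number 23700 with at least 1000 ovary reads, the testis reads were a median of 5.72% of the ovary reads. A constant share of ovary RNA or reads carried into the testis library is argued against as the whole cause. Of 362 unigenes below number 23700 with that many ovary reads, 17 had an upper 95% bound under 2.86%. Among them were the uncharacterized Unigene_17941 at 0.722% and ponzr2 at 0.776%. Oocytes within the sampled testis tissue, or transcripts made by its own germ cells, cannot be told apart. The 90th percentile of the share was 2.61 times the 10th, wider than the bound set for oocytes alike those of the ovary, but oocytes of another stage could give any share, and no library here separates cell types.

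The p-values in the authors' deposited table were a near-exact function of the reads. Of 2071 pairs of read numbers held by more than 1 unigene, 2069 had 1 p-value. Among 22109 unigenes with 7 neighbours within 0.3 on the log2 scale, 8 had a p-value more than 2 times below their neighbours' median, and no other differed by more than 1.25 times. These were foxk2, sox9a, zp2.2, EGR2B, mapk14a, NROB1, fbxo43 and gata6, and all 8 are in the authors' lists. For 6 of them, 10 times the deposited p-value fell within the range of their neighbours. In the authors' deposited table gata6 and rnf40, both with 2 ovary and 96 testis reads, had 0.0256 and 0.0956. For NROB1 and zgc:110158, both with 4 ovary and 38 testis reads, the authors' deposited table gave 0.0398 and 0.398. For sox9a the authors' deposited table gave 0.0212 and its neighbours had a median of 0.230. In the testis list, the deposited log2 fold change differed from log2 of the values in the same row by more than 0.001 in 133 of 171 unigenes, by up to 0.09. In all 133 the deposited one was higher, and in 100 it equalled, within 0.001, log2 of the values of another unigene of the list. The values themselves equalled those of the expression table for all 24 shared unigenes, and the p-value differed from that in the expression table for 16 of the 24 shared unigenes. The ovary list had 0 such differences. The reason for these values was not tested.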
